A study of Mus musculus with 9 samples.

How the data were processed

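Messenger RNA was profiled on 9 Affymetrix mouse arrays, 1 per sample. Per the labels' protocols, bone marrow cells of 129/SvEv mice were grown for 9 to 12 days with GM-CSF, a growth factor that turns them into dendritic cells, and purified DNA from tumor cells was delivered with a lipid transfection reagent for 7 h before total RNA was taken. Biotin-labelled cRNA was made from 6 ug of total RNA. The labels give 3 groups of 3 samples: wild-type cells in media, wild-type cells given tumor DNA, and STING knockout cells given tumor DNA. STING is the adaptor protein that relays the detection of DNA in the cytosol. Knockout cells in media and cells given the transfection reagent alone were not analysed here, so the effects of the DNA and of the reagent were not separated. Each group holds samples numbered 1 to 3. The labels do not say whether these came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical.

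The deposited values are linear signal intensities from the MAS5 algorithm, per the submitters' processing notes. Its version and the array's genome build are not given in the sources used here. In the deposited intensities the mean between the 2nd and 98th percentiles was 499.8 on each array, so the arrays had been scaled to a common level. No detection calls were used here, and a value near the floor cannot be told from background. The table held 45101 probe sets, 64 of them controls. Of the others, 34945 carried 1 gene symbol, 932 carried several and 9160 carried none in the platform annotation, and a gene was named only from a probe set with 1 symbol. The entrez numbers of 34741 probe sets matched the RefSeq gene table for GRCm38.p6, which changed 0 symbols and otherwise served only to find which genes neighbour each other.

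Signals were analysed as log2(signal + 16). All fold changes are on this scale, which understates the change of genes with low signals. Control probe sets were removed, probe sets whose mean over the 9 arrays was above the 40th percentile (5.67 in log2) were kept, and the probe set with the highest mean stood for each gene. This left 27022 probe sets, of which 22792 were named, and 12586 genes. Linear models were fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), without the replicate number, and 2-sided p-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison. A gene was called at an adjusted p below 0.05. The comparisons were tumor DNA against media in wild-type cells, knockout against wild-type cells under tumor DNA, and knockout cells under tumor DNA against wild-type cells in media. Because each pair of comparisons shares arrays, overlaps and correlations are given beside 100 simulations of unchanged groups with the same sharing. Such groups give almost no called genes, so these simulations cannot show what sharing adds to an overlap of called genes. The arrays were too few to split the shared group.

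For 32 gene lists, limma's camera compared the members' change with that of all other genes, 2-sided, with a preset correlation of 0.01, for lists with at least 5 measured members. Its p-values were adjusted over all lists and comparisons together. Camera with an estimated correlation and limma's fry, which asks whether a list's genes move one way on balance, were alternatives. For each list the number of genes called is also given adjusted over the list alone.

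The genes named were fixed by a rule: in each comparison the 8 largest rises and the 8 largest falls among called genes whose 3 values in one group all lay above the 3 in the other, in each called list the 3 called members with the smallest adjusted p, and a set of sensors, interferons, cytokines and costimulatory genes named whatever their result. Of that set, Isg15 had no probe set with a single symbol and was not analysed here. Genes outside the rule are said to be so. The lists, the rule, the tests and the alternatives were chosen before the data were examined, except for the tests marked otherwise in the closing section and the combination of an estimated correlation with the replicate number.

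Samples of the same number deviated together. The correlation of residuals from the group means was 0.17 to 0.49 over the 9 pairs of arrays with the same number and -0.42 to 0.14 over pairs with different numbers, and each of the 9 arrays correlated best with one of its own number. The numbers, which come from the sample titles, were therefore taken to pair the samples, and a fit with the number as a block is given where it changes a call or moves a count by over 1.5 times. A spiked hybridisation control (BioB) read 406 to 552 on the arrays numbered 1 and 115 to 189 on the others, so number 1 was treated as a possible batch of its own, holding 1 array of each group.

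The models were tested on simulated data for 12586 genes in which 200 were changed by known amounts. For tumor DNA against media in wild type, 50% of changes of 1 log2 unit and 94% of changes of 4 units were recovered, with 11 false calls among 123. For knockout against wild type under tumor DNA the shares were 36% and 98%, with 2 false calls among 110. For the knockout against wild-type media they were 30% and 96%, with 5 false calls among 105. The simulated noise was independent between arrays, and far fewer genes were called than in the first 2 comparisons of the data, so these shares need not hold there. The number of arrays limits the precision. The alternatives were other filters, offsets of 0 and 64, quantile normalization, median centring, other variance models, array weights, other ways of treating several probe sets of a gene, the replicate block, the 2 compared groups alone, stricter thresholds, and leaving out each array and each replicate number. Figures were drawn with matplotlib 3.10.9.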

Results

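Transcript levels were measured in dendritic cells grown from the bone marrow of 129/SvEv mice, in 3 groups of 3 arrays: wild-type cells in media, wild-type cells transfected for 7 h with DNA from tumor cells, and STING knockout cells transfected with the same kind of DNA. The comparisons ask which transcripts differ after tumor DNA and which of these differences depend on the presence of STING, the adaptor of the cytosolic DNA-sensing pathway. Over the 12586 genes tested, arrays of one group correlated at r = 0.955 to 0.978 across genes. Wild-type arrays with and without DNA correlated at 0.886 to 0.934, and knockout arrays with DNA correlated with wild-type media arrays at 0.934 to 0.972. Genes are not independent replicates, so these values only describe the arrays. The ratio of 3' to 5' probe sets was 0.80 to 0.90 for Gapdh and 1.04 to 1.14 for actin, a measure of RNA quality.

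Sting1, the gene targeted in the knockout, read 246, 336 and 327 signal units in the 3 knockout arrays with tumor DNA, 2260, 1060 and 1160 in wild-type cells with DNA, and 1520, 1080 and 646 in wild-type media cells. The knockout was lower than DNA-treated wild type by a log2 difference of -2.17 ± 0.35 (SE, n = 3 per group, limma adjusted p = 0.0016). In wild type Sting1 differed with DNA by 0.45 ± 0.35 (adjusted p = 0.35). For the knockout against wild-type media the difference was -1.72 ± 0.35 with an adjusted p of 0.094, which became 0.032 with the replicate block (range over all alternatives other than leaving out arrays 0.020 to 0.14). A second Sting1 probe set read 203, 285 and 331 in the knockout and 543 to 1430 in wild type. Whether either probe set lies within the altered part of the gene is not known here, and a probe set outside that part would not check the knockout. Cgas, which encodes the DNA sensor upstream of STING, was higher with tumor DNA in wild type by 1.08 ± 0.23 (adjusted p = 0.0064) and lower in the knockout under DNA by a difference of -0.90 ± 0.23 (adjusted p = 0.014). Against wild-type media the knockout differed by 0.18 ± 0.23 (adjusted p = 0.96), and the other Cgas probe set by -0.55. The call in the knockout under DNA ended without wild-type DNA array 1 or knockout array 2, with an adjusted p of up to 0.059.

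In wild-type cells tumor DNA raised the type I interferon genes, with list medians of 7.91, 3.19 and 5.47 for the 3 replicate numbers. Ifnb1, which encodes interferon beta, went from 47.3 to 72.4 signal units in media to between 5210 and 21600 with DNA, a log2 rise of 7.19 ± 0.42 (SE, n = 3 per group, limma adjusted p = 3.7e-05). Ifna2 rose by 7.16 ± 0.73, Ifna4 by 6.68 ± 0.74 and Ifna5 by 5.52 ± 0.76, from media signals near the floor. The media signals of these genes were not shown to lie above background, so the sizes depend on the offset of 16 added to each signal and are not measured folds. With offsets of 64 and 0 they were 6.46 and 7.56 for Ifnb1, 5.52 and 9.08 for Ifna2, and 4.18 and 6.81 for Ifna5. Of the 7 measured interferon genes 6 rose, and Ifna1, outside the naming rule and named after its value was seen, differed by 0.05 ± 0.43 (adjusted p = 0.94). The list's camera adjusted p was 1.8e-06, and its adjusted p was 0.28 with an estimated correlation.

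Genes that interferon induces were also higher. For each list a count adjusted over the list alone is added where it differed from the count over all genes. Of 49 interferon-stimulated genes 40 rose and 0 fell (43 and 0 adjusted over the list alone), with a median log2 change of 2.18. Slfn4 rose by 4.34 ± 0.41, Oasl1, an antiviral oligoadenylate synthetase-like gene, by 3.98 ± 0.38 and Isg20, an exonuclease, by 3.91 ± 0.39. Ifit1 rose by 2.33 ± 0.68 (adjusted p = 0.026), a call lost without any of the wild-type DNA arrays or media array 1 or 2 (up to 0.076) and with quantile normalization (0.052, the highest over the alternatives, from 0.0011). The list's camera adjusted p was 3.5e-24, and its adjusted p was 0.28 with an estimated correlation. All 11 guanylate-binding proteins and immunity-related GTPases, which act against intracellular pathogens, rose, with a median of 2.55 (camera adjusted p = 3.7e-09, adjusted p = 0.28 with an estimated correlation). They included Gbp8 (3.26 ± 0.52), Igtp (2.84 ± 0.42) and Gbp2 (2.13 ± 0.31). Among 8 interferon regulatory factors 4 rose and 1 fell, 5 and 1 adjusted over the list alone (camera adjusted p = 0.016, adjusted p = 0.28 with an estimated correlation), with Irf7, an amplifier of interferon production, up by 3.08 ± 0.43, Irf5 by 0.74 ± 0.14 and Irf2 by 0.67 ± 0.18. Another Irf5 probe set differed by -0.09, and with the mean of its probe sets the Irf5 call ended (adjusted p = 0.073, range over the alternatives 0.0012 to 0.073). The Irf2 call ended without media array 1 or 2 (up to 0.058).

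**Figure D1:**
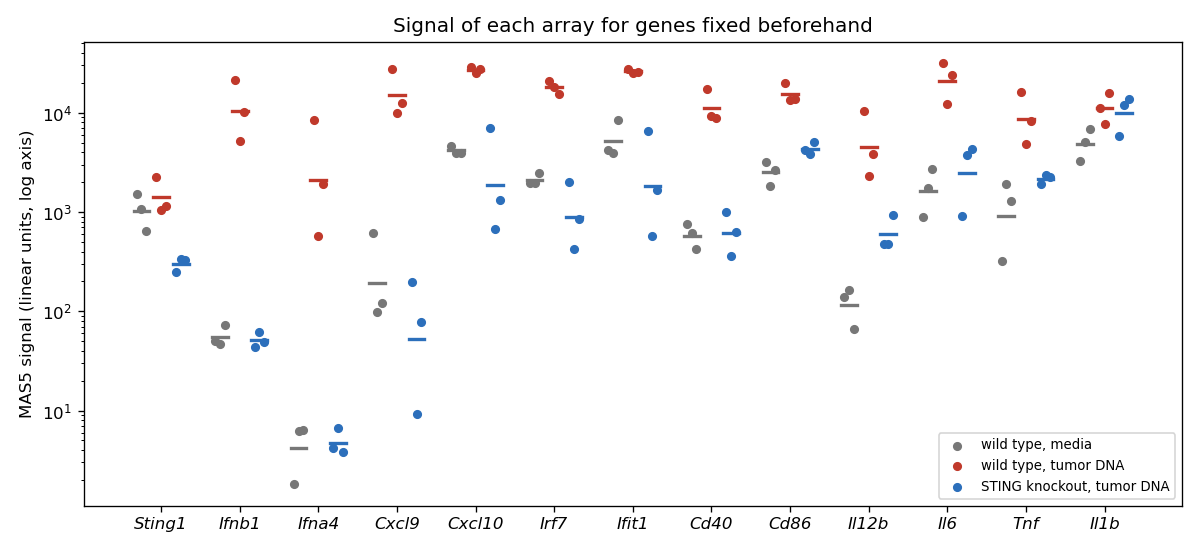
Signal of each of the 9 arrays (points, log axis, MAS5 units) with the geometric mean of each group of 3 (bars) for genes fixed beforehand, in wild-type cells in media, wild-type cells with tumor DNA and STING knockout cells with tumor DNA. Ifnb1 lay between 5210 and 21600 in wild-type cells with DNA and between 43.3 and 62.5 in knockout cells with DNA, while Il1b ranged from 5890 to 13800 in knockout cells with DNA.

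Cytokine, chemokine and costimulatory genes rose as well. Of 23 proinflammatory cytokines 14 rose and 0 fell (15 and 0 adjusted over the list alone), among them Il12b, a subunit of interleukin 12, by 5.10 ± 0.52, Tnfsf10 by 3.92 ± 0.52 and Tnfsf4 by 3.01 ± 0.26. Il6 rose by 3.68 ± 0.60, Tnf by 3.20 ± 0.59, Il12a by 1.81 ± 0.48 and Il1b by 1.20 ± 0.38 (adjusted p = 0.035). The Il1b call was lost with quantile normalization (0.083) and without the variance trend (0.053), over a range of 0.0037 to 0.083, and without media array 1 or 2 or wild-type DNA array 1 or 3 (up to 0.12). That of Il12a was lost without media array 1 or wild-type DNA array 1 or 3 (up to 0.062). The list's camera adjusted p was 6.7e-11, and its adjusted p was 0.23 with an estimated correlation. Of 25 chemokines 8 rose and 0 fell (camera adjusted p = 5.8e-07, adjusted p = 0.21 with an estimated correlation). These included the T cell attractants Cxcl9 (6.14 ± 0.82), Cxcl11 (4.81 ± 0.26), Cxcl10 (2.70 ± 0.65) and Ccl5 (1.90 ± 0.31), and the monocyte attractant Ccl12 (3.77 ± 0.49). Of 24 maturation and costimulation genes 12 rose and 0 fell (camera adjusted p = 3.7e-09, adjusted p = 0.21 with an estimated correlation). The costimulatory receptor Cd40 rose by 4.25 ± 0.38 and the T cell costimulator Cd86 by 2.62 ± 0.23.

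Genes of class I antigen presentation and of cell death rose as well. Of 17 class I genes 14 rose and 0 fell (camera adjusted p = 3.4e-10, adjusted p = 0.28 with an estimated correlation), with the peptide transporter subunits Tap1 and Tap2 up by 2.36 ± 0.31 and 1.87 ± 0.25 and Tapbpl by 2.32 ± 0.22. The other Tap1 probe sets differed by 1.76, 0.58 and -0.02, that of Tapbpl by 1.03 and 1 of the 4 others of Cflar by -0.02. Class II genes did not pass the test (2 of 15 higher and 1 lower, camera adjusted p = 0.43). Of 22 death and inflammasome genes 16 rose and 0 fell, 17 and 0 adjusted over the list alone (camera adjusted p = 1.2e-10, adjusted p = 0.090 with an estimated correlation), including the necroptosis effector Mlkl (2.27 ± 0.15), the DNA sensor Aim2 (1.93 ± 0.22) and Casp8 (1.21 ± 0.11). Of 22 NF-kappaB pathway genes 14 rose and 0 fell, 16 and 0 adjusted over the list alone (camera adjusted p = 4.8e-09, adjusted p = 0.28 with an estimated correlation), with Cflar up by 1.97 ± 0.17, the feedback inhibitor Tnfaip3 by 1.73 ± 0.24 and Tank by 1.02 ± 0.15. Of 21 negative regulators of cytokine signalling 10 rose and 0 fell (camera adjusted p = 3.5e-07, adjusted p = 0.21 with an estimated correlation), with Socs1 up by 3.68 ± 0.40, Dusp1 by 1.46 ± 0.19 and Zfp36 by 1.20 ± 0.20.

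Metabolic lists moved both ways. Of 20 genes of cholesterol synthesis and uptake 11 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.99, led by the sterol carrier Stard4 (-2.32 ± 0.31), Msmo1 (-1.69 ± 0.25) and Lss (-1.18 ± 0.17). The other Msmo1 probe set differed by -0.54. The camera adjusted p of the list was 0.00016, and the adjusted p was 0.44 with an estimated correlation. Of 21 glycolysis genes 6 rose and 0 fell (camera adjusted p = 6.8e-05, adjusted p = 0.30 with an estimated correlation), with the hexokinase Hk3 up by 1.73 ± 0.16, Pfkp by 1.35 ± 0.18 and Pfkfb3 by 1.33 ± 0.22. Of 44 oxidative phosphorylation genes 12 fell and 0 rose, 5 and 0 adjusted over the list alone (camera adjusted p = 0.020, adjusted p = 0.66 with an estimated correlation), among them Ndufs7 (-1.08 ± 0.18), Ndufb10 (-0.74 ± 0.16) and Ndufa8 (-0.68 ± 0.15). The list's median was -0.30, against -0.20 for the median of all genes, and was -0.46 with quantile normalization and 0.01 with median centring. Over all genes 2973 of 12586 were called lower. The list's call ended without the arrays numbered 3 (adjusted p = 0.13). With median centring the calls of Ndufb10 and Ndufa8 ended at adjusted p = 0.059 and 0.062, the highest of their alternatives, the lowest being 0.0023 and 0.0019. Of 24 immediate early and AP-1 genes 7 rose and 2 fell (camera adjusted p = 0.0059, adjusted p = 0.28 with an estimated correlation), with Batf2 up by 2.52 ± 0.22, Klf6 up by 1.15 ± 0.16 and Batf down at -1.29 ± 0.21. This list's call ended without the arrays numbered 1 (adjusted p = 0.059), and its median was -0.08 in number 2. Of 22 NRF2 and oxidative stress genes 6 rose and 2 fell (camera adjusted p = 0.028, adjusted p = 0.44 with an estimated correlation), with Keap1 (0.96 ± 0.15), Sqstm1 (0.99 ± 0.22) and Txn1 (0.49 ± 0.10) up. The NRF2 call ended with quantile normalization, which gave the list a median of -0.02 (adjusted p = 0.60, range over the alternatives with the preset correlation 0.026 to 0.60). It also ended without the filter (0.089) and without the arrays numbered 1 (0.22), and the list's median was -0.16 in number 2. The Txn1 call ended with quantile normalization too (0.093, range 0.0031 to 0.093).

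Outside the lists the rise named by the rule was Nts, which encodes neurotensin, at 5.07 ± 0.46. The falls named by the rule were Sesn1, a p53 target (-3.45 ± 0.39), Tacc2 (-3.29 ± 0.25), the sodium-proton exchanger Slc9a9 (-2.89 ± 0.79), the inhibitory checkpoint receptor Vsir (-2.88 ± 0.34), Mmachc (-2.78 ± 0.33), Abcd2 (-2.74 ± 0.49), Marveld1 (-2.73 ± 0.37) and the sialyltransferase St6gal1 (-2.73 ± 0.32). Among marker lists of other cell types, 3 of 9 T and NK cell markers rose (Klrk1 3.54 ± 0.26, Gzmb 1.87 ± 0.58, Cd247 1.15 ± 0.27; camera adjusted p = 0.0055, adjusted p = 0.28 with an estimated correlation), as did 3 of 11 plasmacytoid dendritic cell markers (Bst2 1.85 ± 0.30, Tcf4 1.25 ± 0.26, Tlr7 1.16 ± 0.23; camera adjusted p = 0.040, adjusted p = 0.28 with an estimated correlation). The plasmacytoid list, whose member Bst2 is also in the interferon-stimulated list, was not called without the arrays numbered 2 (adjusted p = 0.064). Gzmb was not called without wild-type DNA array 1 or 3 or media array 2 or 3 (adjusted p up to 0.12), nor with an offset of 0 (0.078, range 0.020 to 0.078). Slc9a9 was not called without media array 1 or wild-type DNA array 2 or 3 (up to 0.066), and its other probe sets differed by -1.75, -0.63 and -0.09. Other probe sets also differed less for St6gal1 (-0.48), Vsir (-1.65), Sqstm1 (0.45), Pfkp (0.52 in 1 of 2 others), Marveld1 (-1.45, -0.63 and -0.80), Abcd2 (-1.01, 0.32 and -1.16), Sesn1 (-0.73 in 1 of 3 others) and Cd247 (-0.19 and -0.25 in 2 of 3 others).

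Besides the interferons, Nts, Tacc2, Gzmb, Il12a, Cd247, Abcd2, Mmachc and Slc9a9 had a mean signal below the median of the arrays in the lower group, so their sizes depend on the offset too. With offsets of 64 and 0 Nts was 3.55 and 6.99, and Tacc2 -1.91 and -5.08.

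In total 4224 genes were called in wild-type cells given tumor DNA, 1251 higher and 2973 lower. In 46.4% of genes all values of one group lay above those of the other, where chance gives 10%. The median gene shifted by -0.20 log2 units, and the split was 1371 higher and 2207 lower with quantile normalization (median gene -0.10) and 2038 higher and 1451 lower with median centring (0.11). Camera compares a list with all other genes and so is relative to this shift. Without the arrays numbered 1 there were 998 higher and 2026 lower. Leaving out replicate number 2 or 3 lowered the total to 2398 or 1492. Without number 3 the calls of Tnf, Irf5, Zfp36, Cd247, Ndufa8, Tcf4, Sqstm1, Ndufb10, Tlr7, Irf2, Il1b, Il12a, Cxcl10, Ifit1, Slc9a9 and Gzmb ended, at adjusted p from 0.052 for Tnf to 0.18 for Gzmb, with 0.11 for Cxcl10. Without number 1 those of Txn1, Cd247, Sqstm1, Il1b and Il12a ended (up to 0.11), and without number 2 those of Il1b, Gzmb, Cd247 and Irf2 (up to 0.096).

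**Figure D2:**
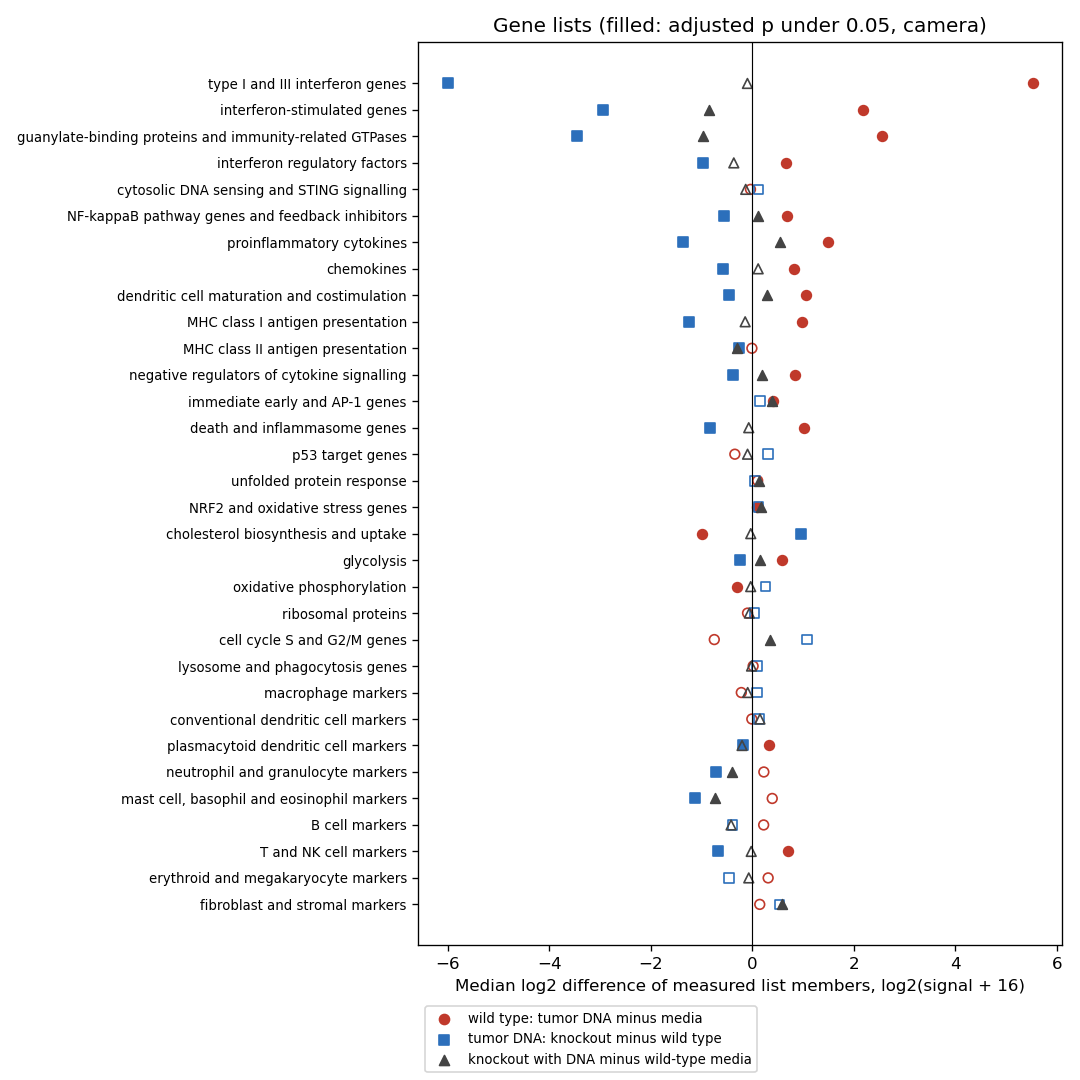
Median log2 difference of the measured members of each of the 32 gene lists in the 3 comparisons (circles, squares and triangles; filled where the camera adjusted p was below 0.05 with the preset correlation, open otherwise). Interferon-stimulated genes lay at 2.18 in wild type with DNA against media, at -2.95 in knockout against wild type under DNA, and at -0.87 in knockout with DNA against wild-type media.

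Under tumor DNA the interferon genes, and the genes that interferon induces, were lower in STING knockout cells than in wild-type cells. Ifnb1 was lower by a log2 difference of -7.29 ± 0.42 (SE, n = 3 per group, limma adjusted p = 1.5e-05), Ifna2 by -7.31 ± 0.73 and Ifna4 by -6.67 ± 0.74. The knockout signals were not shown to lie above background, and with offsets of 64 and 0 these values were -6.52 and -7.69, -5.57 and -9.76, and -4.99 and -8.79. Of the 7 measured interferon genes 6 were lower and 0 higher (camera adjusted p = 1.3e-06, adjusted p = 0.28 with an estimated correlation). Of 49 interferon-stimulated genes 48 were lower, with a median of -2.95 (camera adjusted p = 2.0e-31, adjusted p = 0.28 with an estimated correlation), among them Oasl1 (-5.01 ± 0.38), Isg20 (-4.87 ± 0.39), Ifit1 (-3.80 ± 0.68) and Usp18 (-3.48 ± 0.52). Xaf1 differed by -8.04 ± 0.22, but its other probe set differed by -0.81. The Xaf1 knockout signals, 46.7 to 72.4 units, were not shown to lie above background either, so the size depends on the offset. All 11 guanylate-binding proteins and GTPases were lower (camera adjusted p = 4.7e-11, adjusted p = 0.28 with an estimated correlation), with Iigp1 at -6.04 ± 0.69, Igtp at -3.59 ± 0.42 and Gbp7 at -2.65 ± 0.30. Of 8 interferon regulatory factors 5 were lower and 2 higher (camera adjusted p = 0.0069, adjusted p = 0.28 with an estimated correlation), with Irf7 at -4.30 ± 0.43, Irf2 at -1.25 ± 0.18 and Irf5 at -0.71 ± 0.14. The Irf5 call ended with the mean of its probe sets (adjusted p = 0.096, range over the alternatives 0.0014 to 0.096).

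Chemokine, cytokine and maturation genes were also lower in the knockout. Of 25 chemokines 7 were lower and 0 higher (camera adjusted p = 1.9e-05, adjusted p = 0.25 with an estimated correlation): Cxcl9 differed by -7.57 ± 0.82, Cxcl11 by -6.64 ± 0.26, Ccl12 by -4.47 ± 0.49, Cxcl10 by -3.86 ± 0.65 and Ccl5 by -1.63 ± 0.31. Of 23 proinflammatory cytokines 11 were lower and 0 higher, 12 and 0 adjusted over the list alone (camera adjusted p = 1.6e-07, adjusted p = 0.28 with an estimated correlation), with Tnfsf10 at -5.16 ± 0.52, Tnfsf4 at -2.34 ± 0.26, Il15 at -3.74 ± 0.45, Il6 at -3.07 ± 0.60, Il12b at -2.89 ± 0.52 and Tnf at -1.99 ± 0.59 (adjusted p = 0.029). The Tnf call ended without any of the knockout arrays or wild-type DNA array 1 or 3 (up to 0.11). Il12a differed by -1.38 ± 0.48 with an adjusted p of 0.052, which was 0.029 with the replicate block (range over the alternatives 0.029 to 0.093). It was also below 0.05 with an offset of 64, median centring or array weights, without media array 1 or wild-type DNA array 2 (down to 0.016), and without number 2 (0.048). Il1b differed by -0.17 ± 0.38 (adjusted p = 0.77). Of 24 maturation genes 9 were lower and 1 higher (camera adjusted p = 3.3e-05, adjusted p = 0.28 with an estimated correlation), with Cd40 at -4.16 ± 0.38, the interleukin 15 receptor chain Il15ra at -3.63 ± 0.34, Marcksl1 at -1.63 ± 0.15 and Cd86 at -1.84 ± 0.23.

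Of 17 class I genes 14 were lower (camera adjusted p = 1.2e-10, adjusted p = 0.28 with an estimated correlation), including Tap1 (-2.85 ± 0.31), Tapbpl (-2.47 ± 0.22) and Psmb9 (-2.27 ± 0.26). Other probe sets differed by -1.69, -0.33 and -0.02 for Tap1 and by -1.11 for Tapbpl, and those of Marchf1 by 0.03 and -0.77. Of 15 class II genes 2 were lower and 1 higher, with Rfx5 at -1.34 ± 0.22, Marchf1 at -1.12 ± 0.13 and Ifi30 at 0.72 ± 0.18 (camera adjusted p = 0.0098, adjusted p = 0.45 with an estimated correlation, and 0.13 with quantile normalization, the alternatives with the preset correlation ranging from 0.0082 to 0.13). The Ifi30 call ended with median centring (0.085, range 0.0013 to 0.085) and without wild-type DNA array 1 or 3 (up to 0.053). Of 22 death and inflammasome genes 15 were lower, 16 adjusted over the list alone (camera adjusted p = 3.4e-10, adjusted p = 0.090 with an estimated correlation), including Mlkl (-2.93 ± 0.15), Aim2 (-2.00 ± 0.22) and Casp8 (-1.22 ± 0.11). Of 22 NF-kappaB pathway genes 10 were lower and 1 higher, 13 and 1 adjusted over the list alone (camera adjusted p = 5.8e-07, adjusted p = 0.30 with an estimated correlation), with Cflar at -1.83 ± 0.17, the adhesion molecule Icam1 at -1.10 ± 0.19 and Tank at -1.07 ± 0.15. Of 21 negative regulators 8 were lower (camera adjusted p = 6.2e-05, adjusted p = 0.24 with an estimated correlation), with Socs1 at -3.72 ± 0.40 and Trim30a at -1.70 ± 0.29. Of 20 cholesterol genes 10 were higher and 0 lower, 14 and 0 adjusted over the list alone (camera adjusted p = 0.00035, adjusted p = 0.44 with an estimated correlation), with Stard4 at 2.06 ± 0.31, Msmo1 at 1.66 ± 0.25 and Lss at 1.16 ± 0.17. Of 21 glycolysis genes 5 were lower (camera adjusted p = 0.0047, adjusted p = 0.44 with an estimated correlation, and 0.10 with quantile normalization, from 0.0014 over the alternatives), with Hk3 at -1.58 ± 0.16, Pfkfb3 at -1.17 ± 0.22 and Hif1a at -0.62 ± 0.10 (its other probe sets -0.53, -0.25 and -1.68).

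Marker lists of other cell types differed between these groups too. T and NK cell markers were lower in 3 of 9, or 4 adjusted over the list alone (Klrk1 -3.35 ± 0.26, Gzmb -2.39 ± 0.58, Cd247 -1.17 ± 0.27; camera adjusted p = 0.0047, adjusted p = 0.28 with an estimated correlation), and plasmacytoid dendritic cell markers in 3 of 11 (Bst2 -2.40 ± 0.30, Tcf4 -1.90 ± 0.26, Tlr7 -1.71 ± 0.23; camera adjusted p = 0.019, adjusted p = 0.28 with an estimated correlation). The latter call ended without the arrays numbered 2 (adjusted p = 0.053), and Bst2 is also in the interferon-stimulated list. Of 20 neutrophil markers 2 were lower, or 1 adjusted over the list alone, Stfa3 at -1.68 ± 0.28 and Mpo at -1.08 ± 0.35 (camera adjusted p = 0.0095, adjusted p = 0.59 with an estimated correlation), and the list's median was 0.18 in number 2. That count is near the share over all genes, where 1224 of 12586 were called lower. Of 13 mast cell, basophil and eosinophil markers 4 were lower, with Hdc at -4.46 ± 0.68 and Fcer1a at -1.99 ± 0.45, and 1 was higher, Siglecf at 1.27 ± 0.32 (camera adjusted p = 0.0080, adjusted p = 0.44 with an estimated correlation). Outside the naming rule, Hdc, Fcer1a and Siglecf differed by 4.14, 0.24 and -1.11 in wild type with DNA against media. In the knockout against wild-type media they differed by -0.32, -1.74 and 0.17. The Mpo call ended without any wild-type DNA array but number 3, any knockout array or media array 2 (adjusted p up to 0.14), and without the filter (0.062, range 0.0044 to 0.062). That of Siglecf ended with quantile normalization and median centring (up to 0.052, from 0.00046). With the replicate block the cell cycle list, with 4 of 41 genes higher (0 adjusted over the list alone), was also called higher (adjusted p = 4.0e-05 against 0.082 without the block, range 4.0e-05 to 0.092, with adjusted p = 0.83 with an estimated correlation and 0.47 with that and the block), although its share of called genes was below that of all genes (2746 of 12586 higher). So was oxidative phosphorylation (0.042 against 0.065, range 2.8e-06 to 0.064, with adjusted p = 0.75 with an estimated correlation and 0.69 with that and the block). It was also called higher with quantile normalization, without the filter and without the arrays numbered 2. Its median of 0.25 was 0.39 with quantile normalization and -0.01 with median centring.

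The rises named by the rule in the knockout under DNA were Trim12a (4.19 ± 0.45), the T cell costimulatory receptor Tnfrsf9 (3.99 ± 0.51), Tacc2 (3.93 ± 0.25), Spint1 (3.75 ± 0.33), Junos (3.57 ± 0.63), Trim5 (3.19 ± 0.47), Fblim1 (3.06 ± 0.36) and Fcrls (3.06 ± 0.76). BC023105 was lower at -6.12 ± 0.65. The wild-type DNA signals of Trim12a, Tacc2, Junos and Trim5 (2.18 to 33.6 units) were not shown to lie above background, so the sizes and their order depend on the offset. With offsets of 64 and 0 Tacc2 was 2.45 and 5.76, Junos 2.37 and 4.74, and Trim5 2.09 and 4.37, and Trim12a was 2.79 with 64. The same holds for the knockout signals of Cxcl9, Hdc, Gzmb, Fcer1a and Cd247, whose means lay below the array median. Probe sets disagreed for Trim12a, where the other differed by 0.22 and was the one tested with an offset of 0 (adjusted p = 0.64, range over the alternatives 7.6e-05 to 0.64), and for Tnfrsf9, where the others differed by 5.67 and -1.03. They differed less for Msmo1 (0.34), 1 of 4 others of Cflar (-0.27) and 1 of 5 others of Tcf4 (-0.76), another Irf5 probe set differed by 0.10, and those of Cd247 by 0.52, -0.25 and -0.93. In all 3970 genes were called, 2746 higher and 1224 lower, around a median gene shift of 0.20. All values of one group lay above those of the other in 46.0% of genes, where chance gives 10%. The split was 2140 higher and 1361 lower with quantile normalization and 1456 higher and 1805 lower with median centring. Without the arrays numbered 1 it was 2107 and 1107, and without number 2 or 3 the total was 2256 or 1379. Without number 3 the calls of 17 of the genes named by the rule ended, among them Tnf (adjusted p = 0.17), Gzmb, Fcrls, Cgas, Cxcl10 (0.060), Ccl5 (0.060), Junos, Ifit1 (0.059), Pfkfb3, Fcer1a and Trim30a. Without number 1 those of Gzmb, Cd247, Ifi30 and Mpo ended (up to 0.12), and without number 2 those of Fcrls, Cd247, Mpo, Cgas and Siglecf (up to 0.12).

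Most of the genes raised by tumor DNA in wild type were lower in the knockout. Of the 1251 raised genes 960 (76.7%) were called lower, where independent lists of these sizes would share 122 and simulated unchanged groups with the same shared arrays gave a mean of 0.02. Of the 2973 lowered genes 2269 were called higher, against 649 for independent lists and a mean of 0 in the simulations. Both comparisons use the wild-type arrays with DNA, so part of the excess may come from sharing them. Across genes the log2 differences of the 2 comparisons had a covariance of -0.64, against -0.062 in the simulations. The overlap was 604 without replicate number 2 and 367 without number 3.

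The size of the response left in the knockout was measured for the 726 genes raised at least 1 log2 unit in wild type, as the difference between knockout with DNA and wild-type media over the wild-type change. Its median was -0.003 (quartiles -0.21 and 0.19), with values of 0.08, -0.06 and -0.05 for the 3 replicate numbers (SD 0.08). With the genes chosen on the other 2 numbers the values were 0.05, -0.08 and -0.08. Of the 726 genes 612 were called lower in the knockout than in wild type under DNA, 63 kept a ratio above 0.5 (Il1b had 0.86), and 1 was still called higher than in wild-type media. That gene, Pla1a, was named after its values were seen and rose by 3.48 in wild type and by 1.68 in the knockout (adjusted p = 0.033). The wild-type media cells stand in for knockout cells in media, so a difference between genotypes at rest is included in this ratio.

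**Figure D3:**
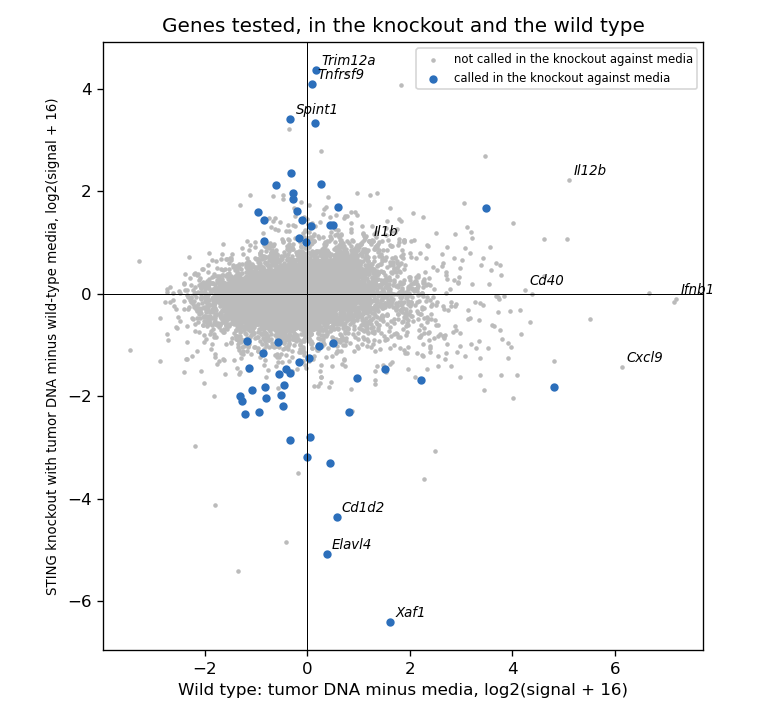
Log2 difference of each of the 12586 genes in wild-type cells with tumor DNA against media (horizontal axis) and in STING knockout cells with tumor DNA against wild-type media (vertical axis). The 54 genes called in the knockout against media (blue) include Xaf1, Elavl4 and Cd1d2 below the axis, while Ifnb1 lies at 7.19 on the horizontal axis and -0.10 on the vertical axis.

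Knockout cells given tumor DNA differed from wild-type media cells in few genes, and the interferon genes were not among them. Ifnb1 differed by -0.10 ± 0.42 (SE, n = 3 per group, limma adjusted p = 0.99), Ifna4 by 0.01 ± 0.74, Cd40 by 0.08 ± 0.38, Ccl5 by 0.27 ± 0.31 and Cxcl9 by -1.43 ± 0.82 (adjusted p = 0.78), while the other Cxcl9 probe set differed by 0.62. The other cytokine and costimulation genes fixed beforehand to be named did not pass either: Il12b differed by 2.22 ± 0.52 (adjusted p = 0.17; 0.015 with array weights, range 0.015 to 0.38), Tnf by 1.21 ± 0.59, Il1b by 1.03 ± 0.38, Cd86 by 0.79 ± 0.23 (adjusted p = 0.34; 0.038 with array weights, range 0.038 to 0.63), Il6 by 0.60 ± 0.60 and Il12a by 0.44 ± 0.48. The genes that did differ included Trim12a (4.37 ± 0.45), Tnfrsf9 (4.09 ± 0.51), the protease inhibitor Spint1 (3.42 ± 0.33), Trim5 (3.33 ± 0.47), Zfp593 (2.35 ± 0.23), Efhd2 (2.14 ± 0.14), Cd300ld (2.12 ± 0.24) and Amacr (1.96 ± 0.32). The falls named by the rule were Xaf1 (-6.42 ± 0.22), Elavl4 (-5.08 ± 0.41), Cd1d2 (-4.36 ± 0.23), Dpys (-3.31 ± 0.21), Tmem87a (-3.19 ± 0.21), the tyrosine-breakdown enzyme Fah (-2.86 ± 0.48), the cell cycle inhibitor Cdkn2a (-2.79 ± 0.37) and Hddc3 (-2.34 ± 0.30). The other Xaf1 probe set differed by 1.56 and the other Dpys probe sets by -0.14 and 0.86, whereas the other Elavl4 probe sets differed by -4.01 and -4.57. The Xaf1 knockout signals of 46.7 to 72.4 units were not shown to lie above background. The other probe sets of Tnfrsf9 differed by 5.29 and -0.84, that of Trim12a by 0.44, that of Hddc3 by -0.51, that of Efhd2 by 1.05 and that of Zfp593 by 0.97. In the lower group Trim12a, Trim5, Amacr, Cd1d2, Elavl4, Fah and Hddc3 had mean signals below the array median, so their sizes depend on the offset: with offsets of 64 and 0 Cd1d2 was -2.86 and -6.14, and Elavl4 -3.83 and -6.28. The Trim5 call ended with an offset of 0, at adjusted p = 0.064 (range over the alternatives 0.0036 to 0.064). Trim12a was not called with an offset of 0 either (adjusted p = 0.84, range 0.00047 to 0.84), but there its other probe set was the one tested.

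Several of these calls ended when a single array was left out. Without media array 3 the calls of Tnfrsf9 (adjusted p = 0.054), Cdkn2a (0.068) and Hddc3 ended, and that of Hddc3 also without knockout array 3 (up to 0.066). The Trim5 call ended without any media array or knockout array 3 (up to 0.067). The Amacr call ended without any media array, wild-type DNA array 1 or knockout array 2 or 3 (up to 0.18), and the Fah call without any of 7 of the 9 arrays, all but wild-type DNA array 1 and knockout array 1 (up to 0.19). With only the 2 groups compared Tnfrsf9 (0.055, range 0.00037 to 0.055) and Amacr were not called, nor were Fos and Nr4a1, which are given with their list, and with the mean of probe sets Dpys was not (0.062, range 1.6e-05 to 0.062). Amacr was also not called without the filter or with an offset of 0 (range 0.0061 to 0.062), nor Fah without the filter, with an offset of 64, with quantile normalization or without the variance trend (range 0.0018 to 0.063).

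In this comparison 15 of the 32 lists were called, and with an estimated correlation the adjusted p of these 15 was between 0.21 and 0.78. The interferon-stimulated genes were lower (median -0.87, camera adjusted p = 5.9e-12, adjusted p = 0.44 with an estimated correlation), although only Xaf1 of its 49 members was itself called. The median of the interferon-stimulated genes by replicate number was 0.27, -1.48 and -1.26. Ifit1 differed by -1.47 ± 0.68, Irf7 by -1.22 ± 0.43 and Cxcl10 by -1.16 ± 0.65, none of them called. Without knockout array 1 all 3 were called lower (adjusted p = 0.041, 0.018 and 0.0051), as was Cxcl10 without number 1 (0.034). Over the alternatives that kept every array of both groups their adjusted p was 0.15 to 0.74, 0.083 to 0.58 and 0.16 to 0.83. Cxcl11 was lower by a called difference of -1.83 ± 0.26 (adjusted p = 0.017; its other probe set -1.06), in a chemokine list that did not pass (camera adjusted p = 0.64). Guanylate-binding proteins were lower as a list (median -0.97, camera adjusted p = 4.9e-05, adjusted p = 0.44 with an estimated correlation), with no member called and medians by replicate number of 0.16, -1.62 and -1.60. Immediate early genes were higher, with Nr4a1 at 1.35 ± 0.20 and Fos at 1.10 ± 0.17 called among 24, 4 adjusted over the list alone (camera adjusted p = 2.2e-06, adjusted p = 0.21 with an estimated correlation). This was the only list of the 15 that fry also called (adjusted p = 0.030). The Nr4a1 call ended without media array 1 or 3 or knockout array 2 or 3 (up to 0.12), and the Fos call without any media array, wild-type DNA array 3 or knockout array 3 (up to 0.18). Both ended with only the 2 groups compared, Nr4a1 at 0.070 (range 0.0028 to 0.070) and Fos at up to 0.065 (range 0.0049 to 0.065), and Fos also without the variance trend. Maturation genes (median 0.29, only Tnfrsf9 called, camera adjusted p = 8.4e-05, adjusted p = 0.28 with an estimated correlation) and proinflammatory cytokines (median 0.54, no member called over all genes, 1 of 23 higher adjusted over the list alone, camera adjusted p = 0.00067, adjusted p = 0.36 with an estimated correlation) were higher as lists. Neutrophil markers (median -0.41) and mast cell, basophil and eosinophil markers (median -0.74) were lower and fibroblast markers higher (median 0.58), with 0 members called besides 1 lower mast cell marker adjusted over the list alone, and with camera adjusted p of 0.011, 0.037 and 0.044 and adjusted p of 0.60, 0.58 and 0.71 with an estimated correlation. Without the arrays numbered 1 the neutrophil and mast cell calls ended (adjusted p = 0.26 and 0.36), and without number 3 the fibroblast call did (0.76). The medians of these lists were -1.01, 0.23 and -0.39, then -1.27, 0.09 and -0.45, then -0.02, 0.12 and 1.40 for numbers 1, 2 and 3. The mast cell call also ended with quantile normalization and with offsets of 0 and 64 (up to 0.10, range over the alternatives with the preset correlation 0.0018 to 0.10), and the fibroblast call with quantile normalization (0.085, range 0.0018 to 0.085).

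In all 54 genes were called, 21 higher and 33 lower, and 948 had an unadjusted p below 0.05. All values of one group lay above those of the other in 13.8% of genes, where chance gives 10%. With the replicate block 176 were called, 86 higher and 90 lower. The count was 72 without the arrays numbered 1, 7 without number 2 and 4 without number 3, and of the genes named by the rule 4, 12 and 14 lost their call without these numbers. Leaving out a single array gave 31, 34 and 18 for wild-type media number 1, 2 and 3, and 131, 27 and 21 for knockout number 1, 2 and 3.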

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

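No result met the rules set for single samples or for differences between effects, since groups of 3 were not tested for outlying samples and the design holds no effect measured in 2 settings. The patterns below were weighed instead. The tests on genome position, on a STING-independent response, on scaling and on intensity distortion, and those on called members and on the sign in each replicate number, were chosen after the result was seen.

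Of the 54 genes that separated stimulated knockout cells from wild-type media cells, 22 had another called gene within 25 placed genes on the same chromosome and 32 did not, where 10000 random draws gave a median of 10 and at most 23 with one (permutation p = 0.0035, 1-sided). The chromosome with the most of them held 14, where the fullest chromosome of each random draw held a median of 7 and at most 14 (permutation p = 0.0004, 1-sided), while among the 53 placed genes with the smallest p for tumor DNA in wild type 8 had such a neighbour (permutation p = 0.74). Of the 54 genes 12 were also called in the same direction in wild-type cells given DNA, fewer than the 27 that a response independent of STING would need to explain most of them. A further 9 were called there in the opposite direction and 33 were not called. Independent lists of these sizes would share 9.88 with the same direction, and simulated unchanged groups with the same media arrays, which give almost no calls, shared 0.01 on average. In knockout against wild type under DNA 48 of the 54 were called in the same direction. A response independent of STING would give no such difference, though both comparisons use the knockout arrays. None of the 54 lay in a segment around the targeted gene carried along with the knockout allele, since 0 were on the chromosome of Sting1. Its share of the placed genes would give only 1.28, so the 0 says little about whether such a segment exists. An effect of such a segment on genes elsewhere was not tested. Genome segments of another strain origin elsewhere in the knockout mice may account for part of the list, though no sequence was examined, and a difference between the genotypes at rest stays open because knockout cells in media were not analysed here.

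More genes were called lower than higher in wild-type cells given tumor DNA. After quantile normalization 2207 genes were called lower and 1371 higher, and after median centring 1451 and 2038, and since both corrections themselves act on this balance and they differ, neither array scaling nor an intensity-dependent distortion was excluded. The median change depended on the signal, from 0.15 in the lowest of 10 classes of genes by mean signal to -0.50 in class 6 and 0.06 in the highest, which such a distortion could give, as could a response of moderately expressed genes. Spiked hybridisation controls, which should be equal, were higher on the wild-type DNA arrays than on the media arrays by 0.25 ± 0.20 log2 units (SD, n = 3 numbers), but they also follow the amount of cRNA loaded, so the share of genes that truly fell stays open.

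Interferon-stimulated genes were lower in stimulated knockout cells than in wild-type media cells as a list. Genome segments of another origin stay open, since the list's median of -0.857 without its 1 called member could hardly have differed from that with it, although 43 of the other 48 members also lay below 0. Loss of resting interferon signalling in the knockout could give this pattern. The outcome set for it, a median under 0 in each replicate number, was not met. The median was 0.268 in number 1, against -1.48 and -1.26 in numbers 2 and 3. A further condition asked for a value above the SD of 0.95 between numbers, which number 1 itself widens, and by that condition the test did not decide. A different mix of cells in the cultures may also contribute: the plasmacytoid dendritic cell markers, without the 1 of 11 that is also in the interferon-stimulated list, followed the list over the 3 numbers at r = 0.985, above the bound of 0.9 set before that correlation was seen. These explanations stay open, and the last test is weak, because with 3 values and 8 lists chance alone passes the bound in 71.1% of cases and the medians of those 10 markers spanned only -0.10 to -0.23. The bound did not count opposite movement. Mast cell, erythroid and neutrophil markers moved opposite to the list (r = -0.96, -0.93 and -0.92, also over 3 values). Their medians spanned -1.27 to 0.09, -0.49 to 0.13 and -1.01 to 0.23. The remaining lists had r from -0.86 to -0.22.

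For each comparison the 6 arrays can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. Every other split also mixes arrays of the 2 real groups, so a real difference widens the spread within its groups and lowers its count. The low counts of the other splits therefore cannot show what chance alone would give. The real split called 4224 genes for tumor DNA in wild type, where 1 split of the 10 gave as many and the highest other gave 1. For knockout against wild type under DNA the values were 3970 and 0, again with 1 split as large. For the knockout against wild-type media they were 54 and 0, with 1 split as large. Of the 9 other splits 3 parted the arrays of all 3 numbers, as the real one does, and gave at most 0 genes in each comparison, and 6 parted those of 1 number and gave at most 1.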

How the results depend on the processing

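The combination of an estimated correlation with the replicate block was chosen after seeing the data. No called named gene reversed direction in the counts below, which left out the fit of every probe set by itself. Probe sets not used did differ in sign for some called genes. In the knockout against wild-type media such probe sets gave 1.56 for Xaf1 (used: -6.42), -0.84 for Tnfrsf9 (used: 4.09) and 0.86 for Dpys (used: -3.31). In wild type with DNA one gave 0.32 for Abcd2 (used: -2.74). Over the alternatives other than leaving out arrays, 2263 of 2303 values of named genes kept their call or stayed within 1 SE, 28 lost it, 10 gained it and 2 moved, and when arrays were left out 147 of 2148 lost it, 7 gained it and 21 moved. Of the estimates that were not called, 23 crossed 0 under some alternative. The count for tumor DNA in wild type, that for knockout against wild type under DNA and their overlap stayed within 1.5 times under the other filters, offsets, scalings, variance models, array weights and the replicate block. They exceeded that when every probe set was fitted by itself (7284, 6796 and 1738, from more features tested), with a log2 change of at least 1 (2096, 2059 and 561), and at an adjusted p below 0.01 (2195, 2183 and 568). Leaving out arrays or numbers gave 1492 to 4207, 1379 to 3949 and 367 to 899, the lowest each without number 3, and why number 3 mattered more than number 1 or 2 was not tested. A stable count did not mean the same genes. Of the 4224 and 3970 called genes, 3131 and 3071 were also called with quantile normalization, and 2702 and 2680 with median centring. The smaller count for the knockout against wild-type media depended most on the setting. It was 202 with array weights, 103 by probe set, 30 with only the 2 groups compared, 19 at an adjusted p below 0.01, and 4 to 131 when arrays or numbers were left out. With the replicate block it was 176, and 194 with the block and quantile normalization, both holding the 54 genes of the fit without it. The cause of the change with array weights was not tested. The retained response moved by less than its SD between numbers in every alternative run, from -0.057 without number 1 to 0.056 with median centring.

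The gene list calls rest on the preset correlation. With an estimated correlation 0, 0 and 0 lists were called, and the same with the replicate block (0, 0 and 0), while 5, 7 and 2 lists had an unadjusted p below 0.05 with it and 4, 2 and 1 with the block. Fry called 17, 14 and 1 of the 18, 18 and 15 lists and, over all lists, 19, 15 and 1. The replicate block kept the 18, 18 and 15 list calls and added 2, 2 and 3, and besides these and Il12a and Sting1, given with their values in the results, it changed no other call of a named gene or list. Signals near the floor limit the folds of the interferon alpha genes, whose media values were as low as 1.80 units.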

Other observations

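The neighbour counts with the replicate block and with 1 gene per run, and the genes of the last paragraph, were chosen after the result was seen. Several lists outside the main response did not pass the camera test in wild-type cells given tumor DNA: DNA sensing and STING signalling (7 of 21 higher and 7 lower), p53 targets (5 of 22 higher and 9 lower), the unfolded protein response (6 of 28 higher and 4 lower), ribosomal proteins (0 of 28 higher and 5 lower), lysosome genes (5 of 31 higher and 4 lower), macrophage markers (4 of 19 higher and 3 lower), conventional dendritic cell markers (1 of 16 higher and 1 lower), B cell markers (0 of 12 higher and 2 lower), erythroid markers (3 of 11 higher and 2 lower), neutrophil markers (1 of 20 higher and 1 lower) and fibroblast markers (2 of 19 higher and 0 lower). Their camera adjusted p was 0.068 to 0.82. The test is relative to the other genes, and for DNA sensing, macrophage and conventional dendritic cell markers it pointed up although the median was below 0 (-0.04, -0.22 and -0.01). Adjusted over the list alone, 8 DNA sensing genes and 10 p53 targets were lower, 4 ribosomal genes were lower and 0 neutrophil markers were higher. Fry, which does not compare a list with other genes, called p53 targets (adjusted p = 0.013) and ribosomal proteins (0.034) lower, and it called p53 targets higher in the knockout against wild type under DNA (0.0098). These calls include the shift of the median gene, -0.20 in wild type. There the p53 median was -0.35 as deposited and -0.04 with median centring, and the ribosomal median -0.10 and 0.21. In the knockout under DNA the p53 median was 0.30 and 0.04. With camera, ribosomal proteins passed with quantile normalization (adjusted p = 1.1e-06, range over the alternatives with the preset correlation 1.1e-06 to 0.36), which gave them a median of -0.34. Like every list, they were not called with an estimated correlation. With the replicate block the cell cycle list was called lower (adjusted p = 0.011 against 0.53 without it, range 0.011 to 0.54; adjusted p = 0.92 with an estimated correlation and 0.68 with that and the block), with 2 of 41 genes higher and 2 lower (0 and 0 adjusted over the list alone). Mast cell markers were called higher with the block (0.032 against 0.11, range 0.032 to 0.23; adjusted p = 0.66 with an estimated correlation and 0.52 with that and the block), with 1 of 13 higher and 1 lower.

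In the knockout against wild-type media the remaining called lists were class II genes (median -0.30, camera adjusted p = 0.00020, adjusted p = 0.30 with an estimated correlation), NRF2 genes (0.16, 0.00021 and 0.28), NF-kappaB genes (0.11, 0.011 and 0.60), negative regulators (0.18, 0.011 and 0.29), cell cycle genes (0.35, 0.011 and 0.78), glycolysis (0.15, 0.013 and 0.52) and the unfolded protein response (0.12, 0.021 and 0.56), each given as median, camera adjusted p and adjusted p with an estimated correlation. None of these lists had a called member, and adjusted over the list alone 4 of the 22 NRF2 genes were higher. Without the arrays numbered 1 the calls of the NF-kappaB genes (adjusted p = 0.91) and negative regulators (0.18) ended. Those of the unfolded protein response and cell cycle genes ended without number 1 or 3 (up to 0.21 and 0.31). In number 2 the medians of the NF-kappaB genes, the unfolded protein response and the cell cycle genes were -0.08, -0.02 and -0.12. The replicate block added DNA sensing genes (adjusted p = 0.045, range over the alternatives 0.036 to 0.085), class I genes (0.018, range 0.018 to 0.057) and B cell markers (0.035, range 0.035 to 0.16), all lower. Their adjusted p was 0.30, 0.75 and 0.57 with an estimated correlation, and 0.41, 0.62 and 0.52 with that and the block.

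On the chromosome with the most called genes, the 14 genes in order along it were Rps6, Cdkn2a, Cdkn2b, Hook1, Elavl4, Hyi, Cap1, Zfp593, Efhd2, Znf41-ps, Zfp991, Clstn1, Tnfrsf9 and Vamp3. Those outside the naming rule were chosen after their values were seen. They changed in both directions, from -5.08 for Elavl4 to 4.09 for Tnfrsf9. With 1 gene kept per run of immediate neighbours, 17 of 50 still had a called neighbour, against a median of 8 in random draws (permutation p = 0.019). With the replicate block 115 of 174 did, against a median of 86 (permutation p = 0.0001, the smallest the draws can give).

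Among genes raised in wild type, those with the highest share of the response left in the knockout included Plekhg1 (ratio 1.04), Eno2 (0.96), Ifrd1 (0.94), Plau (0.89), Dusp5 (0.86) and Il1b (0.86), of which all but Il1b were chosen after their values were seen. None of these was called in the knockout against wild-type media, so the ratios carry a wide error.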
